A study of Mus musculus with 32 samples.

How the data were processed

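Polyadenylated RNA of mouse basolateral amygdala was sequenced in 32 libraries. They fall into 8 groups of 4 by age class (adolescent or adult), treatment (control or social defeat) and day (1 or 21), as each sample's title states. The deposited table holds raw read counts and FPKM values (fragments per kilobase of gene model, scaled to sequencing depth) for 40392 mouse Ensembl genes in each library. Per the submitters' processing notes, reads were handled with cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR, with no version given for edgeR and no roles given for the tools. Per the labels' protocols, RNA was selected with oligo(dT) beads. The counts were deposited as whole numbers that sum to a different total in each library. The FPKM values were computed by the authors, and how fragments were assigned to genes and whether strand was used is not given in the sources used here. The processing notes name hg38, a human build, although the deposited gene identifiers are mouse ones. Positions are therefore given as the table lists them, with the build not stated, and 37197 of the 40392 identifiers were found in the mouse gene name table used to check them. All 64 columns of per-library values were matched to samples by name.

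Library totals ranged from 53885799 to 82208892 counts, and 26502 to 28008 genes had at least 1 count in a library. The FPKM values served only as an alternative scale and as a filter on low expression. Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by its default expression filter within groups, which left 23778 genes holding 99.975% of all counts, and libraries were scaled by TMM factors. A single fit of 8 group means, with 24 residual degrees of freedom, gave every comparison by contrasts and quasi-likelihood F tests, 2-sided. P-values were adjusted by the Benjamini-Hochberg method over all tested genes within a comparison, with a threshold of 0.05. Log2 fold changes come from this fit, and their standard errors (SE) were computed as the absolute log2 change divided by the square root of F. Group levels are in CPM, counts scaled to a common library total with TMM factors, as mean ± SD over 4 libraries. The biological coefficient of variation from the common dispersion was 0.185. A gene at 0 counts in all libraries of a group was given a lower bound of its fold with a floor of 3 counts over the group, which covers counting error only.

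The 12 comparisons were the effect of defeat in each age class and day, 4 interactions (age class by defeat at each day, day by defeat in each age class), age class among controls at each day, and day among controls of each age class. The 33 gene lists, with 809 members of which 798 were in the table, covered stress and activity responses, synaptic and channel genes, markers of cell types and neighbouring regions, and metabolic, immune and chromatin genes. They were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists within a comparison. The same lists were tested with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance. A list's score in a library is the mean log2 CPM of its members. Counts within a list are given over all genes tested and adjusted over the list alone. Comparisons, tests, lists, the rule for named genes and most alternatives were chosen before the data were examined.

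Named genes followed a fixed rule. For a defeat effect these were the 10 higher and 10 lower genes with the smallest adjusted p, model names excepted. If fewer than 5 genes passed, they were the 10 with the smallest p. Up to 4 passing members of each list were added, and Fos, Arc, Npas4, Egr1, Bdnf, Crh, Fkbp5 and Nr3c1 were always evaluated. For interactions and control comparisons the limits were 5 in each direction and 2 per list. Members named as passing within a list follow the list tests.

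Alternatives were upper quartile scaling, no filter on low counts, a mean FPKM of at least 5, DESeq2 1.42.0 with its own size factors, limma on log2(FPKM + 0.1) and log2(FPKM + 1) for genes with an FPKM of at least 1 in at least 4 libraries, limma with library weights, a fit of only the groups compared, the replicate number as a block, each library left out in turn, and an unadjusted p under 0.05 with an absolute log2 change of at least 1. Alternatives chosen after seeing the data were a choroid plexus score as a covariate, the Ttr level as a covariate, choroid plexus, striatal and myelin scores as covariates, and leaving out the 11 libraries above 100 CPM of Ttr. The tests were checked on simulated counts for the 23778 genes with 200 changed genes per comparison. In the simulated adult day 1 comparison, 22% of genes changed 1.25-fold, 42% of those changed 1.5-fold, 56% of those changed 2-fold and 72% of those changed 4-fold were recovered, with 1 false call among 100, and 0 of 32 unchanged lists were called by camera. In the simulated adolescent day 1 comparison these shares were 32%, 60%, 62% and 80%, with 3 false calls among 125. Simulated counts were drawn for each gene independently, without correlation between genes and without differences such as that in Ttr between libraries. The simulation therefore cannot show how often camera calls unchanged lists whose genes are correlated. Replicates were compared by chi-square tests of their counts, and no pair within a group differed as little as sampling noise allows. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

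Genes with near-identical copies, among them Hspa1a and Hspa1b, the haemoglobin genes Hba-a1 and Hba-a2, the class I histocompatibility genes H2-D1 and H2-K1, ribosomal protein genes and Gm8113, can share reads, and their values are uncertain to that extent. Without a stated strand, reads of overlapping antisense genes could not be separated. Results of 1 gene list and of some single genes are not reported here.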

Results

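RNA-seq measured gene expression in the basolateral amygdala, a forebrain region involved in fear and emotional memory, of adolescent and adult mice. In each age class, mice that had undergone social defeat, a stress procedure in which a mouse is exposed to an aggressive opponent, were set against controls at day 1 and day 21. Each of the 8 groups held 4 libraries. The design text names ages of 6 and 9 weeks without tying them to the age classes, and the labels do not say from which event the days count. Library totals ranged from 53885799 to 82208892 counts, with 53885799 to 67751519 in adult defeat day 21 and 60337686 to 82208892 in adolescent defeat day 1. Nothing in the labels says that the libraries of a group come from separate animals, so p-values measure the spread between these samples and not necessarily between animals. Every library had Y-linked Ddx3y at 37.1 CPM or more, while Xist, expressed from the inactive X chromosome of females, was at 0.849 CPM or less. Ttr, which encodes transthyretin and is abundant in choroid plexus, exceeded 100 CPM in 11 libraries: all 4 of adolescent defeat day 1 (813 to 1220 CPM), 2 of adult defeat day 1, 1 in each of the 4 control groups and 1 of adolescent defeat day 21. In adult defeat day 21 it lay between 2.32 and 10.9 CPM.

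**Figure D1:**
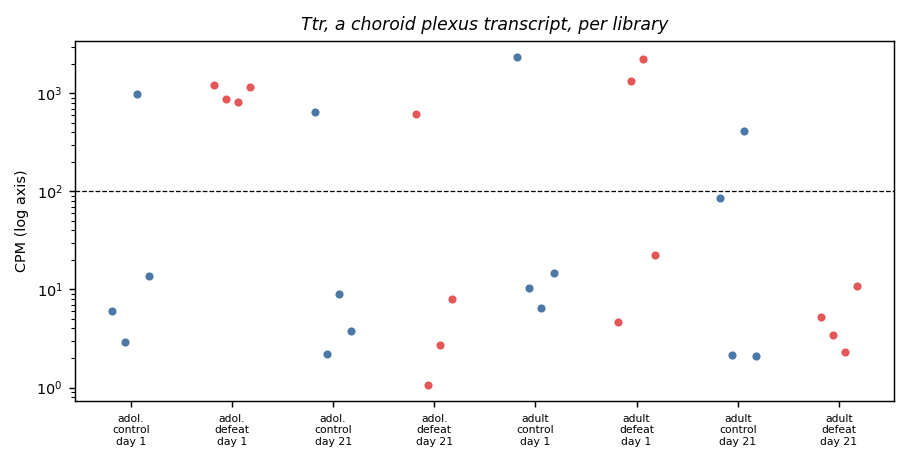
Ttr level (CPM, log axis) by group, 1 point per library (32 libraries; blue, control; red, defeat), with a dashed line at 100 CPM. All 4 libraries of adolescent defeat day 1 lie between 813 and 1220 CPM, whereas the other groups hold 0 to 2 libraries above 100 CPM.

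The 4 defeat comparisons asked how expression differed between defeated and control mice in each age class at day 1 and day 21. Adult mice at day 1 had 84 changed genes, of 23778 tested by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. There were 13 in adolescents at day 1, 3 in adolescents at day 21 and 2 in adults at day 21.

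**Figure D2:**
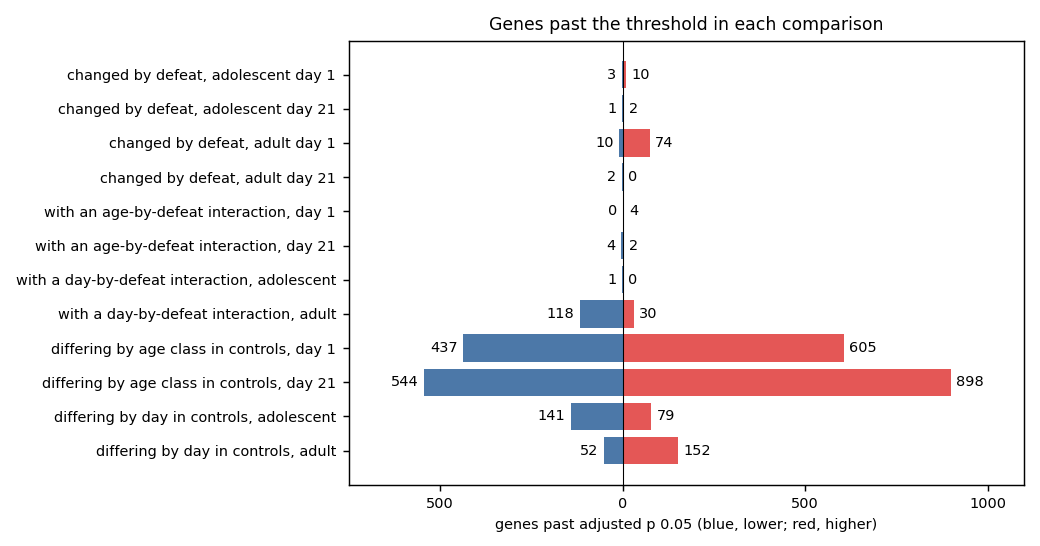
Bars give the number of genes higher (red) and lower (blue) in each of the 12 comparisons at a Benjamini-Hochberg adjusted p under 0.05 (edgeR's quasi-likelihood test, 23778 genes, n = 4 libraries per group). The defeat comparisons gave 13, 3, 84 and 2 genes, and the control comparisons 204 to 1442.

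In adolescents at day 1, glucocorticoid-responsive and clock genes were higher after defeat. Arrdc2, a member of the arrestin domain family, rose 1.81-fold (log2 change 0.85 ± 0.14 SE, adjusted p = 0.0317 by edgeR's quasi-likelihood test, n = 4 per group), from 15.4 ± 2.40 to 27.9 ± 5.76 CPM (mean ± SD). Galnt15, a glycosyltransferase gene, rose by a log2 change of 1.52 ± 0.29, the monooxygenase gene Fmo2 by 1.49 ± 0.28, the kinase gene Map3k6 by 0.99 ± 0.19 and Ptgds, a prostaglandin D2 synthase expressed in meninges and choroid plexus, by 0.90 ± 0.17. The clock-controlled transcription factor genes Dbp and Tef rose by 0.44 ± 0.08 and 0.22 ± 0.04. Fzd2, a Wnt receptor, rose by 0.58 ± 0.11, Adipor2, an adiponectin receptor, by 0.47 ± 0.09 and the class I histocompatibility gene H2-D1 by 0.53 ± 0.10. The 3 lower genes were the matrix metalloproteinase gene Mmp14 (-0.55 ± 0.10), Adgrd1, an adhesion G protein-coupled receptor gene (-0.73 ± 0.14), and Fabp7, a fatty acid binding protein of radial glia and astrocytes (-0.67 ± 0.14). In these 13 genes the 4 defeat libraries lay beyond all 4 control libraries, and adjusted p lay between 0.0317 and 0.0452.

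Of 24 glucocorticoid response genes, 15 rose adjusted over the list alone, and 0 over all genes tested with edgeR (16 had an unadjusted p under 0.05, and DESeq2 called 4). Among the 15 were Sgk1 (1.17 ± 0.29), Tsc22d3 (0.52 ± 0.12), Klf15 (0.50 ± 0.11) and Fkbp5 (0.40 ± 0.11), which encodes a co-chaperone of the glucocorticoid receptor. The list was higher in camera (adjusted p = 1.35e-19) and with an estimated correlation (adjusted p = 0.0018). Of 18 clock genes, 11 rose and 2 fell (Nfil3, -0.34 ± 0.12, and Bmal1, -0.17 ± 0.07) adjusted over the list alone, with 2 over all genes. The clock list was also higher (adjusted p = 0.00184 with an estimated correlation). In these same libraries the choroid plexus list had a median log2 change of 1.31 (adjusted p = 3.12e-07 in camera, adjusted p = 0.291 with an estimated correlation), with Ttr at 2.02 ± 1.99 and no member past the threshold. Blood markers followed, with 5 of 8 higher adjusted over the list alone, among them Alas2 (0.82 ± 0.30), and adjusted p = 0.136 with an estimated correlation. Vessel markers had 5 of 21 higher adjusted over the list alone, led by the glucose transporter gene Slc2a1 (0.58 ± 0.13), and adjusted p = 0.138 with an estimated correlation. Ribosomal protein genes (23 of 57 higher adjusted over the list alone, adjusted p = 0.136 with an estimated correlation) and nuclear genes of oxidative phosphorylation (17 of 41, adjusted p = 0.0635 with an estimated correlation) had median log2 changes of 0.15 and 0.14. For these 4 lists 0 genes passed over all genes with edgeR, 5, 10, 31 and 23 had an unadjusted p under 0.05, and DESeq2 called 0, 1, 2 and 2. Immediate early genes had a median log2 change of -0.23, with 3 of 30 lower adjusted over the list alone (Npas4, -0.69 ± 0.19, Bdnf, -0.48 ± 0.14, and Egr3, -0.20 ± 0.06) and adjusted p = 0.194 with an estimated correlation. Over all genes edgeR called 0 of them, 11 had an unadjusted p under 0.05 and DESeq2 called 0. Fos (-0.72 ± 0.31, adjusted p = 0.6), Arc (-0.50 ± 0.28, adjusted p = 0.746), Crh (-0.27 ± 0.17, adjusted p = 0.788), Egr1 (-0.06 ± 0.14, adjusted p = 0.987) and Nr3c1 (-0.03 ± 0.06, adjusted p = 0.983) did not pass edgeR's test.

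**Figure D3:**
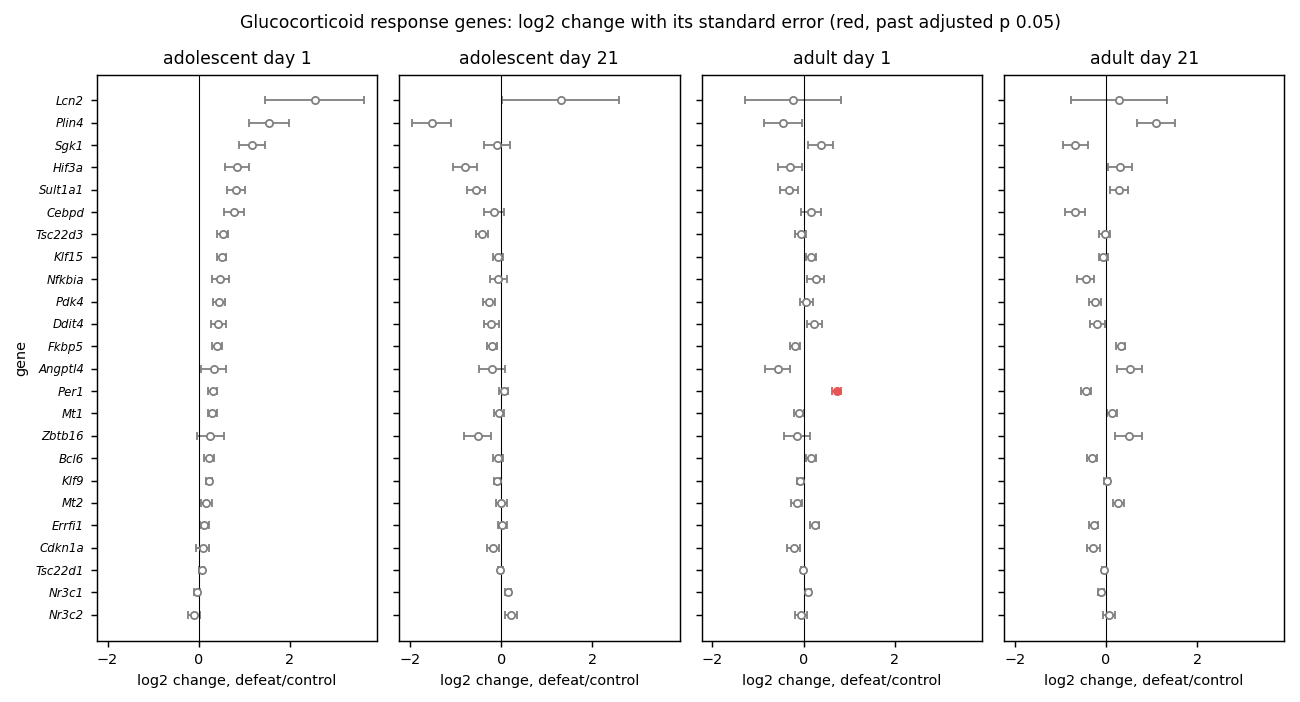
Log2 change (defeat/control, bars for its standard error, n = 4 libraries per group) of each of the 24 glucocorticoid response genes in adolescents and adults at day 1 and day 21, red where adjusted p over all genes tested with edgeR was under 0.05. In adolescents at day 1, 22 estimates lie above 0 and 2 below with 0 red, and the 1 red point is Per1 in adults at day 1 (0.72 ± 0.11).

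The 13 genes stood beside 1772 at an unadjusted p under 0.05, where 1188.9 were due by chance, and 79 with DESeq2. Without control replicates 1, 2, 3 and 4 the count was 0, 0, 0 and 1, and without defeat replicates 1, 2, 3 and 4 it was 1, 36, 8 and 0. It was 0 with the choroid plexus score as a covariate, with no filter on low counts and in a fit of these 2 groups alone. Upper quartile scaling gave 15 genes, 10 higher and 5 lower. The balance was the opposite with limma on log2(FPKM + 0.1) and on log2(FPKM + 1), each with 2 higher and 4 lower.

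In adolescents at day 21, Tmem132e, a transmembrane protein gene, rose 1.35-fold (log2 change 0.44 ± 0.07, adjusted p = 0.0161 by edgeR's quasi-likelihood test, n = 4 per group), from 19.4 ± 1.31 to 26.3 ± 2.61 CPM. Ddx21, an RNA helicase of the nucleolus, rose by 0.35 ± 0.06 (adjusted p = 0.0232), and Tekt4, a gene of cilia and flagella, fell by 1.20 ± 0.21 (adjusted p = 0.0232). Each lay beyond all control libraries in all 4 defeat libraries. Next by p were Eda2r (-3.85 ± 0.73, adjusted p = 0.0599), Zbtb21, Eml2 and Noxred1 (each adjusted p = 0.0764), none of which passed edgeR's test. Cd300ld3 had 0 counts in the control group and 48 in the defeat group, at least 16.4-fold lower in controls with a floor of 3 counts over the group, and did not pass (adjusted p = 0.144). Heat shock and unfolded protein genes were lower in camera (8 of 24 lower adjusted over the list alone, led by the chaperone gene Hspa5 at -0.31 ± 0.07; adjusted p = 0.333 with an estimated correlation). Clock genes had 4 of 18 higher adjusted over the list alone, Dbp (0.36 ± 0.08) and Nr1d1 (0.20 ± 0.05) first (adjusted p = 0.333 with an estimated correlation). Of either list 0 passed over all genes with edgeR, 8 of each had an unadjusted p under 0.05, and DESeq2 called 1 of each. Vessel markers (median log2 change 0.28) were higher in camera, with adjusted p = 0.373 with an estimated correlation, and interferon response genes (0.27) with adjusted p = 0.333 with an estimated correlation. Fkbp5 (-0.20 ± 0.11, adjusted p = 0.895), Fos (-0.33 ± 0.31, adjusted p = 0.985), Arc (-0.40 ± 0.28, adjusted p = 0.965), Npas4 (-0.24 ± 0.19, adjusted p = 0.975) and Nr3c1 (0.15 ± 0.06, adjusted p = 0.828) did not pass edgeR's test. The 3 genes stood beside 1361 at an unadjusted p under 0.05 and 20 with DESeq2 (9 higher, 11 lower). Without control replicates 1, 3 and 4 or defeat replicates 1 and 4 the count was 0, without defeat replicate 3 it was 1, and without control replicate 2 or defeat replicate 2 it was 2.

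In adults at day 1, immediate early genes, which neurons transcribe within minutes of activity, and clock genes were higher after defeat. Egr4 rose 1.88-fold (log2 change 0.91 ± 0.12, adjusted p = 0.000619 by edgeR's quasi-likelihood test, n = 4 per group), from 55.5 ± 3.27 to 104 ± 11.2 CPM. Fosl2 rose by 0.65 ± 0.10, the nuclear receptor gene Nr4a3 by 0.76 ± 0.15 and Egr1 by 0.64 ± 0.14 (adjusted p = 0.0282). In all, 20 of 30 immediate early genes rose and 1 fell adjusted over the list alone, 7 and 0 over all genes, and the list was higher (adjusted p = 0.0166 with an estimated correlation). Of the clock genes, 12 of 18 rose and Bmal1 fell (-0.28 ± 0.07) adjusted over the list alone, 8 rose over all genes, and the list was higher (adjusted p = 4.8e-05 with an estimated correlation). Per1 rose by 0.72 ± 0.11, Per2 by 0.53 ± 0.09, Dbp by 0.52 ± 0.08 and Nr1d1, a repressor of Bmal1, by 0.30 ± 0.05. Egr4 (ENSMUSG00000071341) is listed on chromosome 6 from 85488103 to 85490571, and Per1 (ENSMUSG00000020893) on chromosome 11 from 68986043 to 69000786, both protein coding, with the build not stated.

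In adults at day 1 Fasn, the fatty acid synthase gene, also rose by 0.26 ± 0.04. Chromatin regulators were higher (6 of 36 adjusted over the list alone, 1 over all genes, adjusted p = 0.0455 with an estimated correlation), led by the histone demethylase gene Kdm6b (0.46 ± 0.09). Interferon response genes were higher in camera (5 of 28 adjusted over the list alone, 3 over all genes; adjusted p = 0.0781 with an estimated correlation). Those 3 were Irf9 (0.55 ± 0.11), H2-D1 (0.52 ± 0.11) and H2-K1 (0.50 ± 0.10). Vipr1, a receptor of vasoactive intestinal peptide, rose by 0.43 ± 0.06, the muscarinic receptor gene Chrm4 by 0.41 ± 0.09, Sox11 by 0.33 ± 0.07, Ccdc117 by 0.70 ± 0.12, Pprc1 by 0.46 ± 0.08 and Dedd2 by 0.39 ± 0.06. The lower named genes were Ppp1r10 (-0.31 ± 0.05), Zc3h6 (-0.50 ± 0.09), Otud7a (-0.20 ± 0.05), Nrde2 (-0.38 ± 0.09), Riok2 (-0.26 ± 0.06) and B3galt2 (-0.43 ± 0.10). Among these named genes all 4 defeat libraries lay beyond all 4 control libraries. Of 24 glucocorticoid response genes Per1 was the 1 past the threshold adjusted over the list alone, and Fkbp5 (-0.20 ± 0.11, adjusted p = 0.602) did not pass. Arc (1.01 ± 0.28, adjusted p = 0.133), Npas4 (0.67 ± 0.19, adjusted p = 0.127) and Fos (0.94 ± 0.31, adjusted p = 0.244) were above all controls in all 4 defeat libraries and did not pass edgeR's test, and neither did Nr3c1 (0.10 ± 0.06, adjusted p = 0.666), Bdnf (-0.13 ± 0.14, adjusted p = 0.865) and Crh (-0.11 ± 0.17, adjusted p = 0.918).

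**Figure D4:**
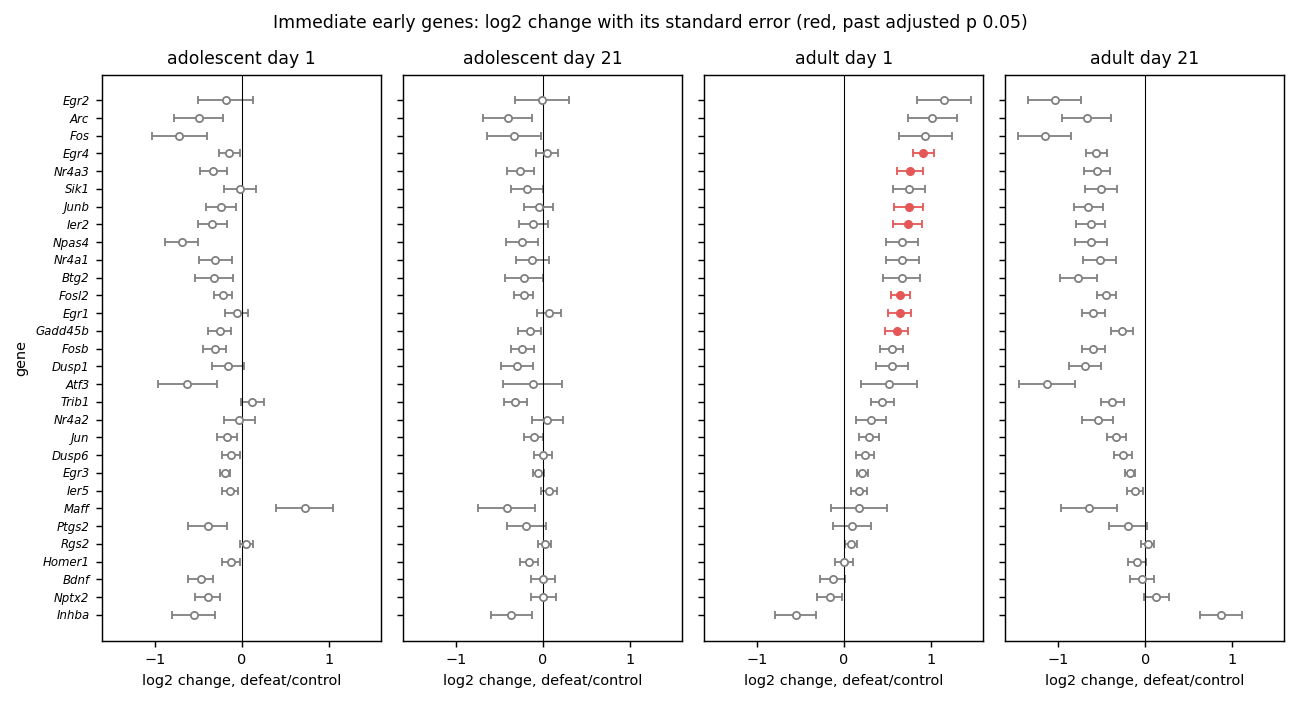
Log2 change (defeat/control, bars for its standard error, n = 4 libraries per group) of each of the 30 immediate early genes in adolescents and adults at day 1 and day 21, red where adjusted p over all genes tested with edgeR was under 0.05. In adults 26 estimates lie above 0 and 4 below at day 1, with 7 red, and 3 above and 27 below at day 21, with 0 red.

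The 84 genes, 74 higher and 10 lower, stood beside 2261 at an unadjusted p under 0.05 and 208 with DESeq2. At an unadjusted p under 0.05 with a log2 change of at least 1 the balance was the opposite, with 110 higher and 160 lower. Without control replicates 1, 2, 3 and 4 the count was 58, 44, 32 and 30, and without defeat replicates 1, 2, 3 and 4 it was 27, 40, 39 and 55. Ttr exceeded 100 CPM in control replicate 1 and defeat replicates 2 and 3, and 13 genes passed without the libraries above that level. A fit of these 2 groups alone gave 20. Without control replicate 4, the immediate early list had adjusted p = 0.0752 with an estimated correlation and chromatin regulators 0.172. Without control replicate 3 or defeat replicates 1, 2 and 3 chromatin regulators had 0.0687, 0.0926, 0.0758 and 0.0628.

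In adults at day 21, the heat shock gene Dnajb1, which encodes a co-chaperone of Hsp70, fell by 0.60 ± 0.10 on the log2 scale (adjusted p = 0.0272 by edgeR's quasi-likelihood test, n = 4 per group), from 83.3 ± 6.48 to 55.0 ± 6.37 CPM. Gm8113, a predicted gene, had 73 counts in the 4 control libraries and 0 in the 4 defeat libraries, at least 22.4-fold lower with a floor of 3 counts over the group (adjusted p = 0.00162). No other gene passed. Immediate early genes were lower as a list (adjusted p = 0.0311 with an estimated correlation), with 21 of 30 lower and 1 higher (Inhba) adjusted over the list alone. Over all genes edgeR called 0 of them, 22 had an unadjusted p under 0.05 and DESeq2 called 4. Egr4 (-0.56 ± 0.12, adjusted p = 0.141), Egr1 (-0.60 ± 0.14, adjusted p = 0.149), Fos (-1.16 ± 0.31, adjusted p = 0.296), Npas4 (-0.62 ± 0.18, adjusted p = 0.434) and Arc (-0.67 ± 0.28, adjusted p = 0.691) were below all controls in all 4 defeat libraries without passing over all genes. Heat shock genes had 9 of 24 lower adjusted over the list alone, 1 over all genes, and adjusted p = 0.0526 with an estimated correlation. Hspa1a had a log2 change of -0.69 ± 0.14 (adjusted p = 0.137). Markers of cortical layers and claustrum (median log2 change -0.18) and of interneurons (-0.09) were lower in camera, each with adjusted p = 0.0526 with an estimated correlation. Markers of striatum and central amygdala, 23 of 23 above 0, were higher in camera (median log2 change 0.24), with adjusted p = 0.527 with an estimated correlation. Crh (0.52 ± 0.17, adjusted p = 0.489), Fkbp5 (0.32 ± 0.11, adjusted p = 0.522), Nr3c1 (-0.11 ± 0.06, adjusted p = 0.859) and Bdnf (-0.03 ± 0.14, adjusted p = 0.99) did not pass edgeR's test, nor did Tmc5, Hhex, Jdp2, Atosa, Gm28557 and 2810030D12Rik (adjusted p = 0.137 or 0.141). Tmc5 and 2810030D12Rik had 0 counts in the control group and were at least 28.6-fold and 12.7-fold lower there.

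The 2 genes stood beside 1537 at an unadjusted p under 0.05 and 40 with DESeq2 (15 higher, 25 lower). Without defeat replicate 1 the count was 29, without control replicates 1, 3 and 4 it was 5, 3 and 4, and without control replicate 2 or defeat replicates 2 and 3 it was 1. The immediate early list had adjusted p = 0.158 with an estimated correlation without defeat replicate 4, 0.0967 without control replicate 2 and 0.0608 without control replicate 4.

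**Figure D5:**
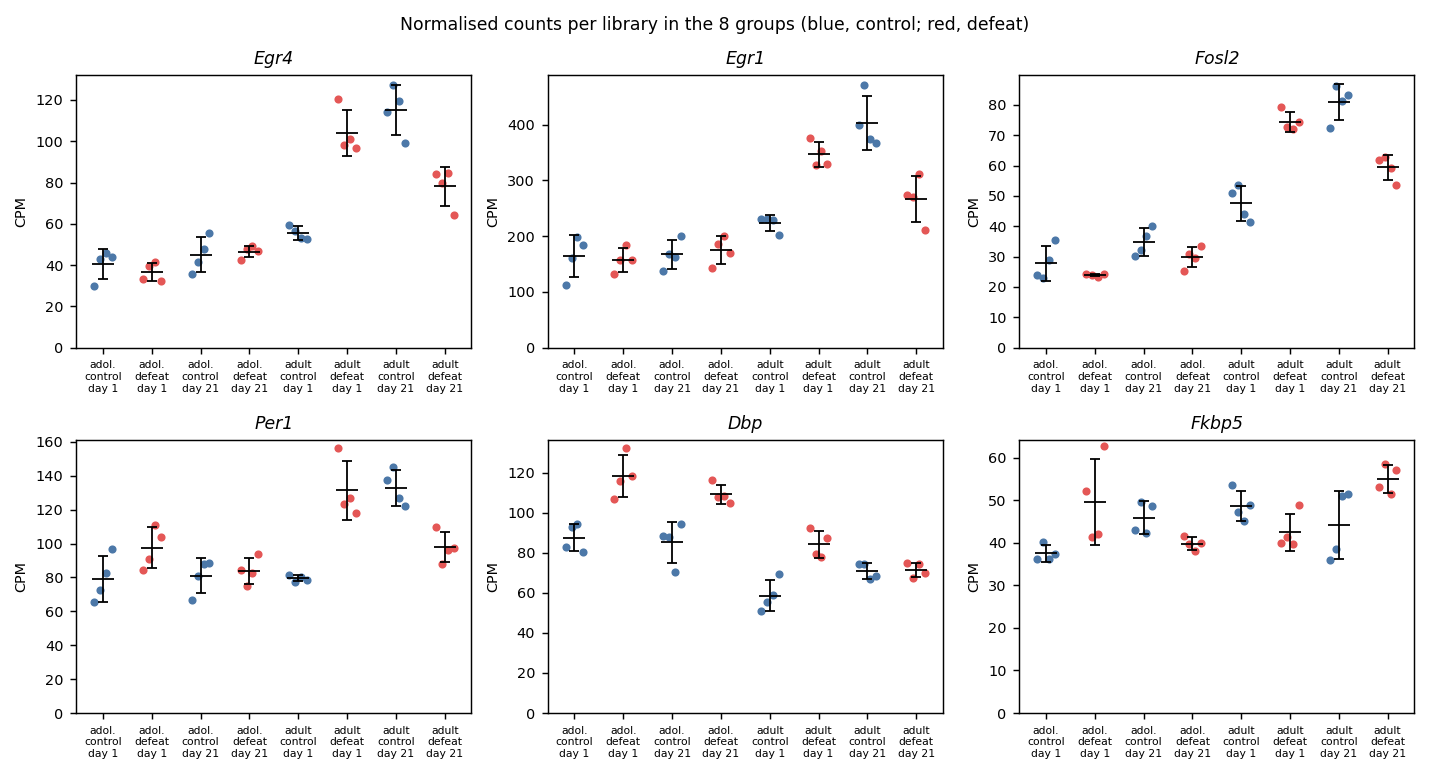
Levels (CPM) of Egr4, Egr1, Fosl2, Per1, Dbp and Fkbp5 in each library by group, with mean and SD (n = 4). Egr4 averaged 55.5 CPM in adult control day 1, 104 in adult defeat day 1, 115 in adult control day 21 and 78.1 in adult defeat day 21.

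Whether the defeat effect differed between age classes was tested as an interaction, adult effect minus adolescent effect. At day 1 Egr4 (1.05 ± 0.17), Fosl2 (0.87 ± 0.15), both with adjusted p = 0.0195 by edgeR's quasi-likelihood test, and Vipr1 (0.47 ± 0.09, adjusted p = 0.0439) had the larger effect in adults. The same held for the gene model Gm44199 (1.45, adjusted p = 0.0195), named here after its value was seen. Immediate early genes moved toward higher values in adults than in adolescents as a list (adjusted p = 0.00638 with an estimated correlation), with 21 of 30 past the threshold adjusted over the list alone and 2 over all genes. The glucocorticoid list moved the other way (adjusted p = 0.04 with an estimated correlation). Adjusted over the list alone, 7 of its 24 genes had the lower effect in adults, among them Fkbp5 (-0.60 ± 0.15) and Tsc22d3 (-0.59 ± 0.17), and Per1 the higher one, while over all genes edgeR called 0, 10 had an unadjusted p under 0.05 and DESeq2 called 2. Chromatin regulators had the higher effect in adults (3 of 36 adjusted over the list alone, adjusted p = 0.033 with an estimated correlation), with 0 over all genes in edgeR, 10 at an unadjusted p under 0.05 and 1 in DESeq2. These 4 genes stood beside 1574 at an unadjusted p under 0.05 and 47 with DESeq2 (32 higher, 15 lower). All 4 adolescent defeat libraries here had Ttr above 100 CPM.

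The day 1 interaction count was 0 without adolescent control replicates 3 and 4, adolescent defeat replicates 1 and 4, adult control replicates 3 and 4, or adult defeat replicate 1, and 1 without adolescent defeat replicate 3. It was 11 without adolescent control replicate 1. The glucocorticoid list lost its call (adjusted p = 0.0702 to 0.111 with an estimated correlation) in 8 of 16 omissions: adolescent control replicates 1, 2 and 3, adolescent defeat replicate 4, adult control replicates 1 and 4, and adult defeat replicates 2 and 3. Chromatin regulators lost it (0.0504 to 0.0855) without adolescent control replicate 1, adult control replicate 4, or adult defeat replicates 1 and 2.

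At day 21 the effect of defeat was higher in adults for Sox9, a transcription factor of astrocytes (0.66 ± 0.11, adjusted p = 0.0178 by edgeR's quasi-likelihood test), and for Acsl3, an acyl-CoA synthetase gene (0.36 ± 0.07, adjusted p = 0.0331). It was lower in adults for Tmem132e (-0.68 ± 0.10, adjusted p = 0.00269), Fam163b (-0.45 ± 0.08, adjusted p = 0.0178) and the laminin gene Lama4 (-0.95 ± 0.18, adjusted p = 0.0331). Gm8113, with 0 counts in adult defeat day 21, was the remaining gene and had the lower effect in adults (adjusted p = 0.0064). Vessel markers had 8 of 21 lower in adults adjusted over the list alone, among them Cdh5 (-0.93 ± 0.25) and Slco1a4 (-0.81 ± 0.19), with adjusted p = 0.184 with an estimated correlation. Over all genes edgeR called 0 of these markers, 9 had an unadjusted p under 0.05 and DESeq2 called 1. The 6 genes, 2 higher and 4 lower, stood beside 1732 at an unadjusted p under 0.05 and 42 with DESeq2 (19 higher, 23 lower). At an unadjusted p under 0.05 with a log2 change of at least 1 the balance was the opposite, with 350 higher and 174 lower. It also turned with choroid plexus, striatal and myelin scores as covariates (23 higher, 9 lower). Without the libraries above 100 CPM of Ttr 0 genes passed. Without adult defeat replicate 1 the count was 32, without adult control replicate 1 it was 11, without adult control replicate 2 or adult defeat replicate 4 it was 2, and without adolescent control replicate 4, adolescent defeat replicates 1 and 3 or adult defeat replicate 2 it was 3.

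Whether the defeat effect differed between days was tested as the effect at day 21 minus that at day 1. In adults 148 genes passed, 30 higher and 118 lower, against 2509 at an unadjusted p under 0.05 and 295 with DESeq2. At an unadjusted p under 0.05 with a log2 change of at least 1 the balance was the opposite, with 333 higher and 227 lower. Of 30 immediate early genes 18 were lower and 1 higher over all genes, 23 and 1 adjusted over the list alone (adjusted p = 0.000972 with an estimated correlation). Egr4 had an interaction of -1.47 ± 0.17 (adjusted p = 3.6e-05 by edgeR's quasi-likelihood test), Egr1 of -1.23 ± 0.19 and Fosl2 of -1.09 ± 0.15. Clock genes were lower (6 of 18 over all genes; 11 lower and 2 higher adjusted over the list alone; adjusted p = 0.000652 with an estimated correlation), with Per1 at -1.16 ± 0.15 and Per2 at -0.72 ± 0.13. Named lower genes from other lists were Dnajb1 (-0.92 ± 0.14), Dnajb5 (-0.48 ± 0.10), Irf9 (-0.82 ± 0.16), H2-D1 (-0.65 ± 0.15), Kdm6b (-0.65 ± 0.13) and Hdac5 (-0.32 ± 0.08). Interferon response genes, 4 of 28 lower adjusted over the list alone and 2 over all genes, had adjusted p = 0.122 with an estimated correlation. The higher genes included Zc3h6 (0.89 ± 0.13), Atosa (0.57 ± 0.10), Zfp143 (0.65 ± 0.12), Ccsap (0.48 ± 0.08) and Ppp1r10 (0.41 ± 0.07). Without adult defeat day 21 replicate 1 the count was 269, without replicate 2 of that group 82, without adult control day 1 replicate 4 88, and without adult control day 21 replicate 2 90. Without the libraries above 100 CPM of Ttr it was 38.

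In adolescents 1 gene differed between days in its defeat effect: Map3k6, at -1.55 ± 0.26 (adjusted p = 0.0454 by edgeR's quasi-likelihood test), against 1181 genes at an unadjusted p under 0.05 and 17 with DESeq2. The glucocorticoid list was lower at day 21 than at day 1 (adjusted p = 0.00077 with an estimated correlation). Adjusted over the list alone, 11 of 24 genes were lower, among them Tsc22d3 (-0.94 ± 0.17), Plin4 (-3.06 ± 0.61) and Fkbp5 (-0.61 ± 0.15). Over all genes edgeR called 0 of them, 12 had an unadjusted p under 0.05 and DESeq2 called 3. The choroid plexus list (median log2 change -1.01, adjusted p = 0.44 with an estimated correlation) and meningeal markers (-0.17, adjusted p = 0.497) were also lower in camera, blood markers had a median log2 change of -0.44 and were not called (adjusted p = 0.158 in camera), and Map3k6 no longer passed with that score as a covariate. The count was 0 without each of the 4 adolescent control day 1 libraries, adolescent control day 21 replicates 2, 3 and 4, adolescent defeat day 1 replicates 1 and 4, or adolescent defeat day 21 replicates 1 and 4. It was 2 without adolescent control day 21 replicate 1 or adolescent defeat day 1 replicate 3, and 8 without adolescent defeat day 1 replicate 2.

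Among controls, adults had higher heat shock and unfolded protein genes than adolescents at both days. Here and in the comparison of days below, age class and day may be confounded with the batch of collection. These differences can therefore not be assigned to age or time alone. At day 1, 18 of 24 were higher over all genes and 21 adjusted over the list alone (adjusted p = 1.85e-05 with an estimated correlation), and at day 21 again 18 and 21 (adjusted p = 0.000903 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, was 2.08-fold higher in adults at day 1 (log2 difference 1.05 ± 0.08, adjusted p = 3.42e-10 by edgeR's quasi-likelihood test, n = 4 per group), at 420 ± 57.4 against 202 ± 13.9 CPM, with Xbp1 at 0.75 ± 0.06, Manf at 0.79 ± 0.08 and Hspa1b at 1.57 ± 0.16. Chordc1 was higher by 0.64 ± 0.06, and Zfp46 (-0.67 ± 0.08), Nr1d1 (-0.42 ± 0.05), Dbp (-0.58 ± 0.08), Zdhhc8 (-0.43 ± 0.06) and Lars1 (-0.34 ± 0.05) were lower. At day 21 immediate early genes were higher in adults (23 of 30 over all genes; 27 higher and 1 lower adjusted over the list alone; adjusted p = 0.00101 with an estimated correlation), with Egr4 at 1.35 ± 0.12, Egr1 at 1.27 ± 0.14 and Fosl2 at 1.21 ± 0.11. Per1 (0.71 ± 0.11), Per2 (0.63 ± 0.09), Bhlhe40 (0.64 ± 0.09) and Sstr2, a somatostatin receptor (0.83 ± 0.14), were also higher. The cold-inducible gene Cirbp (-0.66 ± 0.08), Sox9 (-0.56 ± 0.08) and Zkscan2 (-0.67 ± 0.09) were lower. At day 21 markers of cortical layers and claustrum (2 of 16 over all genes, Nr4a2, which is also on the immediate early list, and Ccn2; adjusted p = 0.273 with an estimated correlation) and of vessels (3 of 21 higher and 1 lower; adjusted p = 0.68) were higher in adults in camera, and markers of striatum and central amygdala lower (median log2 difference -0.24; adjusted p = 0.68). Markers of pallial excitatory neurons were not called (adjusted p = 0.116 in camera), with 2 of 17 higher over all genes, Neurod2 and Nptx1. In day 1 controls the immediate early list was higher in camera (7 of 30 higher and 1 lower over all genes), with adjusted p = 0.476 with an estimated correlation. The glucocorticoid list was higher at both days in camera (5 and 9 of 24 over all genes), with adjusted p = 0.236 and 0.0654 with an estimated correlation. In all, 1042 genes differed at day 1 (605 higher in adults, 437 lower; DESeq2 1500) and 1442 at day 21 (898 and 544; DESeq2 1858). Upper quartile scaling gave 1364 at day 21, 638 higher and 726 lower, so the balance of directions there depended on scaling, and an unadjusted p under 0.05 with a log2 change of at least 1 gave 165 higher and 349 lower. At day 1 the count was 511 without adult replicate 1, 629 without adult replicate 2 and 590 without adolescent replicate 3, and 188 without the libraries above 100 CPM of Ttr, 131 higher and 57 lower. At day 21 it was 874 without adolescent replicate 1, 912 without adult replicate 2, and 451 without the libraries above 100 CPM of Ttr.

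Between days, adult controls differed in immediate early genes, which were higher at day 21 than at day 1 (15 of 30 over all genes; 24 higher and 1 lower adjusted over the list alone; adjusted p = 0.0016 with an estimated correlation). Egr4 was 2.08-fold higher (1.05 ± 0.12, adjusted p = 2.97e-05 by edgeR's quasi-likelihood test, n = 4 per group), Fosb by 0.88 ± 0.13 and Egr1 by 0.85 ± 0.14. Clock genes were higher too (4 of 18 over all genes, 11 adjusted over the list alone, adjusted p = 0.0016 with an estimated correlation), with Per1 at 0.74 ± 0.11. Vessel markers such as Flt1 (1.07 ± 0.19) and Tek (0.89 ± 0.17) were higher (8 of 21 over all genes, 13 adjusted over the list alone; adjusted p = 0.0691 with an estimated correlation). Tfrc, the transferrin receptor gene (-0.38 ± 0.06), Bmf (-0.79 ± 0.14) and Slc43a3 (-1.71 ± 0.35) were lower. Adolescent controls had lower myelin genes at day 21 (7 of 23 over all genes, 18 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), among them Opalin (-0.78 ± 0.16) and Cldn11 (-0.81 ± 0.18). The myelin list was also lower at day 21 in adult controls in camera (median log2 change -0.38, 3 of 23 lower adjusted over the list alone; adjusted p = 0.439 with an estimated correlation), where edgeR called 0 over all genes, 10 had an unadjusted p under 0.05 and DESeq2 called 0. Hspa5 (0.49 ± 0.08), Egr3 (0.39 ± 0.06) and the mitochondrial ribosomal RNA mt-Rnr1 (0.67 ± 0.11) were higher, and Cnksr3 (-0.83 ± 0.11), Smurf1 (-0.32 ± 0.04), Trhde (-0.74 ± 0.12) and the muscarinic receptor gene Chrm3 (-0.69 ± 0.12) lower. Heat shock genes were higher in adolescent controls at day 21 in camera (4 of 24 over all genes, 15 adjusted over the list alone; adjusted p = 0.112 with an estimated correlation). In all, 204 genes differed in adults (152 higher at day 21, 52 lower; DESeq2 551) and 220 in adolescents (79 and 141; DESeq2 579). At an unadjusted p under 0.05 with a log2 change of at least 1 the balance was the opposite in both, with 124 higher and 291 lower in adults and 132 and 127 in adolescents. In adults the count was 108, 100, 84, 86 and 72 without day 1 replicates 1 and 3 and day 21 replicates 2, 3 and 4, and 24 without the libraries above 100 CPM of Ttr. In adolescents it was 140, 97, 92, 96 and 60 without day 1 replicates 1, 3 and 4 and day 21 replicates 2 and 4, 32 without the libraries above 100 CPM of Ttr, and 9 with choroid plexus, striatal and myelin scores as covariates.

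The defeat effects were then correlated across all 23778 genes, which are not independent replicates. P came from 100 relabellings of defeat and control within each age class and day, with Benjamini-Hochberg adjustment over the 4 relations. At day 1 the adolescent and adult effects had Pearson's r = 0.0853 and Spearman's rho = 0.0810 (permutation p = 0.119, adjusted p = 0.158). At day 21 these were r = -0.0778 and rho = -0.0546 (permutation p = 0.0297, adjusted p = 0.0594). Day 1 against day 21 gave r = 0.0397 and rho = 0.0687 in adolescents (permutation p = 0.168, adjusted p = 0.168) and r = -0.0874 and rho = -0.117 in adults (permutation p = 0.0198, adjusted p = 0.0594). None of the 4 passed. Over the 7668 genes with a mean FPKM of at least 5, r was 0.231, 0.0434, 0.174 and -0.294 in the same order (adjusted p = 0.29, 0.842, 0.218 and 0.198), so the size of r, and at day 21 its sign, depended on the genes included. Dbp and H2-D1 were higher in both age classes at day 1, where independent lists of 10 and 74 genes would share 0.0311. No gene passed at both days in either age class by edgeR's test. Of the 74 genes higher in adults at day 1, 66 had a log2 change below 0 at day 21, against 36.9 for genes drawn at random, though these genes are correlated with one another.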

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

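The tests chosen only after the result was seen were the splits of the adolescent day 1 libraries, the 4 tests on the adult immediate early genes, both tests of collection time and the adolescent test of induction. The remaining splits, both tests on the glucocorticoid genes and the adult test of induction were chosen before. The rules of 2 tests were tightened after their values were seen, and each moved an explanation from supported to undecided: the second set of clock genes had to be lower by itself (adult part), and the comparison with adult control day 1 had to hold also with the spread of the 2 groups alone.

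Several measures were checked in each of the 8 groups of 4 libraries, which gave 136 pairings of a measure with a group. In 9 of them, 1 library lay far from the other 3, with a gap of more than 0.829 of the group's range. For normally distributed values chance gives this in about 1 in 20 pairings, or 6.8 of 136. Ttr levels, which ranged from 1.07 to 2342 CPM over the libraries, are not of that kind. Ttr was far above the rest in adolescent control day 1 replicate 3 (982 CPM), adolescent control day 21 replicate 1 (640 CPM), adolescent defeat day 21 replicate 1 (622 CPM) and adult control day 1 replicate 1 (2342 CPM). Egr1 was low in adult control day 1 replicate 4 (202 CPM against 228 to 231 in the others). Nr3c1 was high in adolescent control day 1 replicate 4 (78.9 CPM) and adult defeat day 21 replicate 2 (78.7 CPM). The immediate early score was high in adult control day 21 replicate 2 (5.61) and the clock score in adolescent control day 21 replicate 4 (5.69).

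The defeat effect differed between age classes in 4 genes at day 1 and 6 at day 21, and between days in 1 gene in adolescents and 148 in adults. Between age classes at day 1 it also differed for the lists of immediate early genes (adjusted p = 0.00638 by camera with an estimated correlation), glucocorticoid response genes (0.04) and chromatin regulators (0.033). Between days it differed for the glucocorticoid list in adolescents (0.00077), and for the immediate early (0.000972) and clock lists (0.000652) in adults.

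Other splits of the same libraries showed how often as many genes pass by chance, the real split being among those counted. The rule was a share under 0.05 in each of the 12 comparisons, without adjustment over them. A share of 1 in 35 is the smallest that 35 splits can give, so a first rank does not exclude chance. For adult day by defeat the real split ranked first: 1 of 100 splits gave 148 genes or more, and the highest of the others gave 101. For age by defeat at day 21 the real split did not rank first, although the share was under 0.05. Of 100 splits 2 gave as many as the real 6, and the other of these gave 21. That split, mirrored, differs from the real one by the exchange of 1 control and 1 defeat library in each age class (adolescent control replicate 2 and defeat replicate 3, adult control replicate 1 and defeat replicate 2), and what sets it apart was not tested. The share was over 0.05 for age by defeat at day 1 and for day by defeat in adolescents. In the first, 6 of 100 splits gave as many as the real 4 and the highest other gave 512. In the second, 6 of 100 gave as many as the real 1 and the highest other gave 2. For the defeat effect, the real split ranked first in adolescents at day 1 (1 of 35 splits, 13 genes against 3 in the highest other). It also did at day 21 (1 of 35 splits, 3 genes against 1). Both counts were 0 in a fit of the 2 groups alone and with some single libraries left out. At day 1 the real split is also close to one by Ttr, above 100 CPM in all 4 defeat libraries and 1 control library. In adults the share was over 0.05 at both days. At day 1, 2 of 35 splits gave 84 genes or more, the other one 272. At day 21, 2 of 35 gave 2 or more, the other one 7. The split with 272 genes set control replicates 1 and 2 and defeat replicates 2 and 3 against the other 4 libraries, and it points to a structure of the samples, since all 3 day 1 adult libraries above 100 CPM of Ttr fell on one side. The split with 512 genes divided the adult libraries in the same way. For age class in controls the real split ranked first at day 1 (1 of 35 splits, 1042 genes against 504 in the highest other) and at day 21 (1 of 35, 1442 against 40). It also did for day in controls in adolescents (1 of 35, 220 against 4) and in adults (1 of 35, 204 against 1). These ranks do not separate age class or day from a batch of collection.

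Glucocorticoid response genes were higher in adolescent defeat day 1, the group with Ttr above 100 CPM in all 4 libraries. Against carry-over of choroid plexus as the whole source, the difference of the list score was 0.533 ± 0.126 SE before and 0.51 ± 0.14 after the within-group slope on the choroid plexus score was taken out, though that slope was near 0 (0.00851 ± 0.0208). For a larger share of vessels and blood, 0.32 ± 0.115 stayed after the slopes on those scores were taken out. In this fit nearly all of the fall from 0.533 went with the blood score, as the vessel slope was 0.0194 ± 0.149. That SE leaves open that vessels carry part of the difference too. The slopes of both tests came from all 8 groups. With these 2 groups alone the differences left were 0.544 ± 0.252 and 0.205 ± 0.204, the second within 2 SE of 0. A larger share of vessels and blood can therefore not be excluded as the whole source. A response to circulating glucocorticoid after defeat, set by the treatment the labels name, stays open as a hypothesis and was not tested.

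Immediate early genes were higher than control in adult defeat day 1 and lower in adult defeat day 21. Differing tissue makeup is argued against as the whole source: with choroid plexus, striatal and myelin scores as covariates the difference between days kept an adjusted p of 0.00204 with an estimated correlation, and the list's median was -1.10 against -1.12 without them. Markers of cortex and claustrum and of vessels moved with the list (-0.26 and -0.31 in score). With these 2 scores added, the cortical one without genes of both lists, the adjusted p was 0.0256, the median -1.12, and the difference in list score -0.86 ± 0.23 SE against -0.89 ± 0.17. The slopes on them were 0.12 ± 0.436 and 0.0564 ± 0.198, too uncertain to exclude that tissue makeup carries part of the difference. With these scores added the count of genes was 21 against 148, with 4 immediate early genes lower against 18, while the list's median did not shrink. A deviating adult control day 21 group cannot give the day 1 part, which does not compare those libraries (adjusted p = 0.0166 with an estimated correlation). For the day 21 part it cannot be told apart from an effect of defeat: adult defeat day 21 lay above adult control day 1 by 0.19 in list score, within 2 SE with the spread of all groups (SE 0.12) and beyond 2 SE with that of these 2 groups alone (SE 0.064). A low adult control day 1 group, which could give the day 1 part, was not tested. List scores were 4.87 in adult control day 1 and 5.32 in adult defeat day 1. They were 5.49 in adult control day 21 and 5.06 in adult defeat day 21, so the 2 control groups also differed. An effect of defeat that turns over time stays open, untested.

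Clock genes changed at day 1 in both age classes. Collection of the groups at different clock times stays possible for the adolescent part. There Dbp, Tef, Hlf, Per3, Nr1d1, Nr1d2, Ciart and Bhlhe41 less Bmal1, Npas2, Clock, Nfil3 and Cry1 differed by 0.38 ± 0.06 on the log2 scale. The second set alone differed by -0.11 ± 0.04. The test was chosen after Dbp and Tef had been seen to rise and Nfil3 and Bmal1 to fall. The change of the second set rests largely on Nfil3 and Bmal1, so it gives no independent support. In adults the difference was 0.34 ± 0.06 and the second set moved by -0.036 ± 0.044. Collection time cannot be told apart there from a change of the first set alone, although the difference alone would have met the rule as first set. Sampling times are not in the labels. Induction together with the immediate early genes is argued against in adolescents, whose immediate early score differed by -0.22 ± 0.12. In adults the test cannot decide on such induction for the genes of these 2 sets. There 0.34 ± 0.08 stayed after the slope on that score was taken out, a slope near 0 (0.00693 ± 0.114). That slope came from all 8 groups. The score varied less within adult control day 1 (SD 0.083) and adult defeat day 1 (0.060) than within adolescent controls (0.27 at day 1, 0.28 at day 21). With the 2 adult day 1 groups alone 0.53 ± 0.33 stayed, within 2 SE of 0. Per1 and Per2, which also rose in adults, were in neither set, so the test does not cover them. A shift of the clock by defeat predicts the same as a change of collection time and stays open, untested.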

How the results depend on the processing

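Of 200 values of named genes that passed, 0 reversed under any alternative. With DESeq2, 199 of 199 still passed, with upper quartile scaling 188 of 200, and with a single library left out 1313 of 1824, the others staying in direction. A fit of only the groups compared left 84 of 200 no longer past the threshold, no filter on low counts 50, the choroid plexus, striatal and myelin scores as covariates 59, and leaving out the libraries above 100 CPM of Ttr 109 of 183. Counts of genes under upper quartile scaling stayed within 1.5 times in all 12 comparisons. The covariates and the omission of high-Ttr libraries were chosen after seeing the data. Without the libraries above 100 CPM of Ttr, adolescent day 1, age by defeat at day 1 and day by defeat in adolescents could not be run, since no adolescent defeat day 1 library was left. For the changes below the cause was not tested, except that fewer genes enter with a mean FPKM of at least 5 and fewer libraries when libraries are left out.

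DESeq2 gave 79, 20, 208 and 40 genes for defeat in adolescents at day 1 and 21 and adults at day 1 and 21, 47 and 42 for age by defeat at day 1 and 21, 17 and 295 for day by defeat in adolescents and adults, and 579 and 551 for day in adolescent and adult controls. With no filter on low counts these were 0 (adolescent day 1), 48 (adult day 1), 1 (adult day 21), 0 and 94 (day by defeat, adolescents and adults), 125 and 117 (day in controls). A mean FPKM of at least 5 gave 6 (adolescent day 1), 0 (adolescent day 21), 1 (adult day 21), 10 and 3 (age by defeat, day 1 and 21), 0 (day by defeat, adolescents), 735 (age in controls, day 21), 336 and 115 (day in controls). A fit of only the groups compared gave 0, 0 and 20 (adolescent day 1, adolescent day 21, adult day 1), 0 (age by defeat, day 1), 96 (day by defeat, adults), 264 (age in controls, day 1), 136 and 81 (day in controls). The unadjusted p under 0.05 with a log2 change of at least 1 gave 224, 263, 270 and 285 for defeat, 340 and 524 for age by defeat, 311 and 560 for day by defeat, 271 and 514 for age in controls and 415 for day in adult controls. With this rule more genes were lower than higher, against the balance otherwise reported, for defeat in adolescents at day 21 (80 higher, 183 lower) and adults at day 1 (110 and 160), age by defeat at day 1 (159 and 181), age in controls at day 21 (165 and 349) and day in adult controls (124 and 291), and more were higher for defeat in adults at day 21 (180 and 105), age by defeat at day 21 (350 and 174), day by defeat in adults (333 and 227) and day in adolescent controls (132 and 127). The balance also turned in adolescents at day 21 with DESeq2 (9 higher, 11 lower), in adults at day 21 without control replicate 1 (4 and 1), for age by defeat at day 21 with a mean FPKM of at least 5 (2 and 1), with all 3 scores as covariates (23 and 9), with library weights (5 and 4) and without adult control replicate 1 (6 and 5), and for day in adolescent controls with all 3 scores (7 and 2).

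The choroid plexus score as a covariate gave 0 in adolescents at day 1 and 0 for day by defeat in adolescents, and the Ttr level as a covariate 3 and 0. The choroid plexus, striatal and myelin scores gave 0, 140 and 6 (adolescent day 1, adult day 1, adult day 21), 32 (age by defeat, day 21), 0 (day by defeat, adolescents), 9 and 70 (day in controls). Without the libraries above 100 CPM of Ttr the counts were 0, 13 and 0 (adolescent day 21, adult day 1, adult day 21), 0 (age by defeat, day 21), 38 (day by defeat, adults), 188 and 451 (age in controls), 32 and 24 (day in controls). With limma on log2(FPKM + 0.1) there were 6 genes in adolescents at day 1 (2 higher, 4 lower), 12 for age by defeat at day 1 and 0 for day by defeat in adolescents. With limma on log2(FPKM + 1) there were 6 (2 higher, 4 lower) and 1 (adolescent day 1 and 21), 137 (adult day 1), 12 (age by defeat, day 1), 0 (day by defeat, adolescents) and 331 (day in adolescent controls). Library weights gave 11 in adults at day 21, 8 for age by defeat at day 1 and 0 for day by defeat in adolescents. Of the 149 list calls in camera, 18 held with an estimated correlation, 17 and 19 of such calls were made with the choroid plexus score and with all 3 scores as covariates, and fry made 39.

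With 1 library left out, the counts ranged from 0 to 36 and 0 to 2 (adolescent day 1 and 21), 27 to 58 and 1 to 29 (adult day 1 and 21), 0 to 11 and 2 to 32 (age by defeat), 0 to 8 and 82 to 269 (day by defeat), 511 to 1458 and 874 to 1310 (age in controls), and 60 to 211 and 72 to 281 (day in controls), and list calls from 139 to 165. Correlations of defeat effects ranged from 0.0400 to 0.143 (day 1, adolescent against adult), -0.0945 to -0.0594 (day 21), -0.00605 to 0.0627 (adolescents, between days) and -0.0934 to -0.0665 (adults, between days). The third turned negative without adolescent defeat day 21 replicate 1 (-0.00605), and the second turned positive with a mean FPKM of at least 5 (0.0434), where the others were 0.231, 0.174 and -0.294. Replicate numbers did not pair the libraries: the mean correlation of same-numbered deviations was 0.0014, and 4 of 32 libraries correlated best with their own number. With the replicate block there was 1 gene in adults at day 21 and 2 for day by defeat in adolescents, and other counts stayed within 1.5 times.

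Single genes that reversed had not passed, whereas the lists that turned had been called in camera. The log2 change of Egr1 turned in adolescents at day 1 without control replicate 3 (0.043) or defeat replicate 1 (0.016), and at day 21 without control replicate 1 (-0.019) or defeat replicate 3 (-0.009). Over the libraries left out it ranged from -0.202 to 0.043 and from -0.019 to 0.165. That of Bdnf turned in adolescents at day 21 with the choroid plexus score (0.003), all 3 scores (0.1), library weights (0.007), without the libraries above 100 CPM of Ttr (0.03), and without control replicate 3 (0.081) or defeat replicates 1 (0.034), 2 (0.005) and 3 (0.005). In adults Bdnf turned at day 1 without defeat replicate 1 (0.003), and at day 21 with all 3 scores (0.061), without the high-Ttr libraries (0.049), and without control replicates 3 (0.049) and 4 (0.026) or defeat replicate 4 (0.035), and Crh turned at day 1 without defeat replicate 1 (0.013). Over the libraries left out Bdnf ranged from -0.072 to 0.081 in adolescents at day 21, and in adults from -0.24 to 0.003 at day 1 and -0.161 to 0.049 at day 21, and Crh from -0.208 to 0.013. Lists turned with the adjusted p that follows. With the choroid plexus score these were choroid plexus (0.986, and 0.999 with an estimated correlation) and interferon response (0.986 and 0.999) in adolescents at day 1, and meninges (0.983 and 0.99) and choroid plexus (0.872 and 0.884) for day by defeat in adolescents. With all 3 scores and an estimated correlation they were striatum in adolescents at day 1 (0.912), adults at day 21 (0.772), day by defeat in adults (0.932) and age in controls at day 21 (0.794), myelin in adolescents at day 21 (0.78) and for day in adolescent (0.89) and adult controls (0.979), oxidative phosphorylation in adults at day 21 (0.955) and day in adolescent controls (0.854), and meninges for day by defeat in adolescents (0.933). Striatum in adolescents at day 21 turned without control replicate 3 (0.502; adjusted p 3.74e-07 to 0.581 over the libraries left out), choroid plexus for age by defeat at day 1 without adult control replicate 1 (0.755; 0.000203 to 0.755), and mitochondrially encoded genes for day in adult controls without the high-Ttr libraries (0.926).

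Library totals of 53885799 to 82208892 counts limit genes with few counts most: Gm8113 had 73 counts over 4 libraries, and its lower bound covers counting error only.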

Other observations

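Single members of further lists differed among controls. In adults at day 1, against adolescents, the microglial gene Tmem119 (0.48 ± 0.12, adjusted p = 0.0141 by edgeR's quasi-likelihood test), the GABA-A receptor subunit gene Gabra2 (0.37 ± 0.07), the serotonin receptor gene Htr1b (0.49 ± 0.12), the neuropeptide gene Cartpt (0.74 ± 0.21), Calb1 (0.27 ± 0.06) and Lhx6 (0.29 ± 0.07) were higher, and the serotonin receptor gene Htr6 (-0.45 ± 0.13), Nlgn2 of inhibitory synapses (-0.17 ± 0.04) and Insig1 (-0.35 ± 0.06) lower. At day 21 the corticotropin-releasing hormone receptor gene Crhr1 (0.34 ± 0.09, adjusted p = 0.0139), the adrenergic receptor gene Adra2a (0.43 ± 0.12), the serotonin receptor gene Htr2a (0.31 ± 0.09) and Ifit1 of the interferon response (1.02 ± 0.28) were higher, and Acan of perineuronal nets (-0.50 ± 0.14), the astrocytic gene Aldh1l1 (-0.32 ± 0.08) and Pdgfrb of pericytes (-0.46 ± 0.11) lower. Between days, adolescent controls had lower Tbr1 (-0.54 ± 0.12, adjusted p = 0.0189), Nr4a2 (-0.85 ± 0.18), Gnb4 (-0.57 ± 0.11) and Ifit1 (-1.24 ± 0.28), and higher Tshz2 (0.47 ± 0.09), at day 21.

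Over the 12 comparisons, 149 of the list tests were called by camera and 18 with an estimated correlation. Those 18 included immediate early genes (6), clock genes (4), glucocorticoid response genes (3), heat shock genes (2) and chromatin regulators (2). Lists called in camera that did not hold with an estimated correlation in any comparison included markers of striatum and central amygdala (8 calls, smallest adjusted p = 0.517 with an estimated correlation), microglia (5, 0.498), astrocytes (5, 0.511), meninges (5, 0.197), mitochondrially encoded genes (5, 0.368), inflammation (4, 0.112), oligodendrocyte precursors (1, 0.439), pallial excitatory neurons (2, 0.602) and immature neurons (1, 0.477). The same held for genes of presynaptic release (3 calls, 0.559), monoamine and acetylcholine receptors (2, 0.359), perineuronal nets (2, 0.136), ion channels (2, 0.513), glutamate receptors (1, 0.513), GABA receptors (1, 0.597) and sex-linked genes (1, 0.425). Neuropeptides with their receptors and markers of thalamus and hypothalamus were called in 0 comparisons (smallest camera adjusted p = 0.194 and 0.0666).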
